A study of Homo sapiens with 9 samples.

How the data were processed

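The 9 samples were grouped by the knockdown named in the labels into control, MELK and UBE2C siRNA, 3 arrays each. Per the labels' protocols, PC3 cells were transfected with 50 nM siRNA, total RNA was amplified and biotin-labelled, and the cRNA was hybridized to Illumina bead arrays. The deposited signals are bead intensities per probe on a linear scale, neither background-subtracted nor scaled between arrays, as their values show (background 97.7 to 102 on every array). Per the file headers, each deposited intensity has a detection p-value; how it was computed is not given in the sources used here. The authors' processed values are log2 values with the same quantiles on every array and no background subtraction, found by comparing each column with the same array's intensities; their median was 6.78 on every array, direction is not in question for 1-colour arrays, and centring was not applied. The submitters' processing notes name lumi without a version, role or parameters. In the authors' values 1 probe is blank on every array and 1 on some arrays.

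Intensities were corrected for background and normalized with neqc in limma 3.58.1 (R 4.3.3), which infers the background from the detection p-values, adds an offset of 16, quantile-normalizes and takes log2. The detection p was found to be small both above and below the background level: 2428 to 3108 probes per array had p under 0.01 below it. A probe therefore counted as detected when its p was under 0.01 and its signal above background, and was kept when detected on at least 3 arrays (19511 probes). This filter was chosen after seeing the data and departs from the wording fixed before they were examined, which used the p alone. That literal filter is given as an alternative. Of 47323 probes 30113 had 1 gene in the platform annotation, 8 had several and 17202 had none listed. Symbols were checked by gene number against a RefSeq table of assembly GRCh38.p14, which matched 30074 probes and changed 0 symbols; 39 kept the annotation's symbol. No build is given for the array annotation in the sources used here, so coordinates are not printed. Of the kept probes 4445 without 1 gene were left out of the tests. For the 2960 genes with more than 1 kept probe, the probe with the highest mean log2 over all 9 arrays was used. Other kept probes exist for 17 of the named genes. They gave 25 values, counting a probe once per comparison, and 1 of these values went the other way.

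Group means were fitted to all 9 arrays with lmFit and eBayes (no trend), without a replicate term, because nothing in the labels says that equal replicate numbers share a day. The comparisons were each knockdown against control and MELK siRNA against UBE2C siRNA, with Benjamini-Hochberg adjustment over 11428 genes and a threshold of 0.05 on the adjusted p. This design, 22 gene lists (878 distinct symbols, of which 729 were measured), the rule for named genes and most alternatives were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists. No call holds with an estimated correlation. The fry rotation test, which asks whether a list's genes move on balance one way, called 5 lists for MELK siRNA and 1 for UBE2C siRNA in the 8-array fit and 0 with 9 arrays. Genes named are MELK and UBE2C; in each comparison up to 8 called genes with the largest increase and 8 with the largest decrease whose arrays do not overlap between groups; up to 4 called members of a called list in its direction and 1 in the other; at most 2 called members of a list not called; and up to 6 genes called in the same direction in both knockdowns. A gene not above background on any array of a group is given as a bound: the bright group's mean against, per array, the higher of the lowest detected signal and the probe's own. The bound makes no allowance for sampling error. For RANGRF and CNTROB it equalled the fitted change, which is given instead.

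The 8-array fit leaves out UBE2C siRNA replicate 1, keeps the normalization, probe choice and model, and uses eBayes with an intensity trend and robust hyperparameters. It was added after seeing the data and after its counts were known, and the named genes other than MELK and UBE2C come from it by the same rule. Pairs of arrays of one group shared at most 14 identical signals, so none was counted as a repeat. No slide or scan date was used here, so batches could not be tested.

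The fits were tested on simulated data with 200 changed genes. Each gene's mean came from the 8 arrays and its spread from the 8-array fit. Extra spread was added only to UBE2C siRNA replicate 1, so the simulation favoured the 8-array fit by construction. On 9 arrays the MELK siRNA comparison recovered 0% of changes of 0.5 on the log2 scale, 17.9% of 1 and 75.8% of 2, with 0 false calls; the UBE2C siRNA comparison recovered 0%, 13.4% and 72.7%, with 0 false calls. On 8 arrays the recovery for MELK siRNA was 50.7%, 80.6% and 100%, with 4 false calls. For UBE2C siRNA it was 38.8%, 83.6% and 100%, with 17 false calls beside 26, 56 and 66 recovered changes. Alternatives covered background correction (none, normexp with offset 50), normalization (median scaling, cyclic loess, the authors' values), detection filters, the probe rule, the arrays and groups in the fit, array weights, the prior, thresholds, a replicate block and each array left out in turn. Figures were drawn with matplotlib 3.10.9.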

Results

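Gene expression was measured in PC3 cells, an established human prostate cancer line that grows without androgen, 48 h after transfection with 50 nM siRNA. Each of 3 groups had 3 arrays: a pool against MELK, a protein kinase whose transcript is high in dividing cells; a pool against UBE2C, the ubiquitin-conjugating enzyme that works with the anaphase-promoting complex; and a negative control siRNA. Per the labels, the control siRNA came from another supplier than both pools. Changes against control that both knockdowns share therefore cannot be told apart from an effect of siRNA type or handling. The labels give separate samples but do not say whether these came from separate cultures, so p-values measure the spread between these samples, which may be technical. Between 16559 and 18661 of the 47323 probes were above background on an array, and the 99th percentile of the signal was 83.5 to 108 times the background signal. The small number of arrays limits the precision. After filtering, 11428 genes were tested.

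The targeted transcripts followed the labels on every array. The MELK transcript (probe ILMN_2212909) had a normalized log2 signal of 10.46 ± 0.08 (SD, n = 3) with control siRNA and 9.38 ± 0.06 (SD, n = 3) with MELK siRNA, a log2 fold change of -1.09 (SE 0.19) that left 47.1% of the control level. The UBE2C transcript (probe ILMN_2301083) went from 12.90 ± 0.06 (SD, n = 3) to 11.58 ± 0.07 (SD, n = 3) with UBE2C siRNA, a log2 fold change of -1.32 (SE 0.12) that left 39.9% of the control level. Each was lower in all 3 knockdown arrays than in all 3 controls, and the two-sided exact permutation p was 0.1 for each, the smallest that 3 against 3 arrays can give. In the limma fit of all 9 arrays, the fall of UBE2C passed the threshold (adjusted p = 0.0283), and the fall of MELK did not (adjusted p = 0.884). With 9 arrays the call of UBE2C was lost with median scaling (adjusted p = 0.504), the mean of probes (adjusted p = 0.407), and only 2 groups in the fit (adjusted p = 0.719). It was also lost when any array other than UBE2C siRNA replicate 1 was left out (adjusted p from 0.163 to 0.356), although the log2 fold change stayed between -1.37 and -1.29. A second MELK probe gave -1.11 on the log2 scale, and a second UBE2C probe lay near background in every group. UBE2C differed by -0.06 (SE 0.12, adjusted p = 0.999) between MELK siRNA and control, and MELK by 0.03 (SE 0.19, adjusted p = 0.942) between UBE2C siRNA and control. The latter sign rests on UBE2C siRNA replicate 1: in the 8-array fit without it, with a trended prior, the value was -0.19 (SE 0.10, adjusted p = 0.274). On that array the MELK probes disagreed, with a log2 signal of 10.94 for the tested probe, above all controls, and 8.36 for the second, where the MELK siRNA arrays lay at 8.27 to 8.45.

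**Figure D1:**
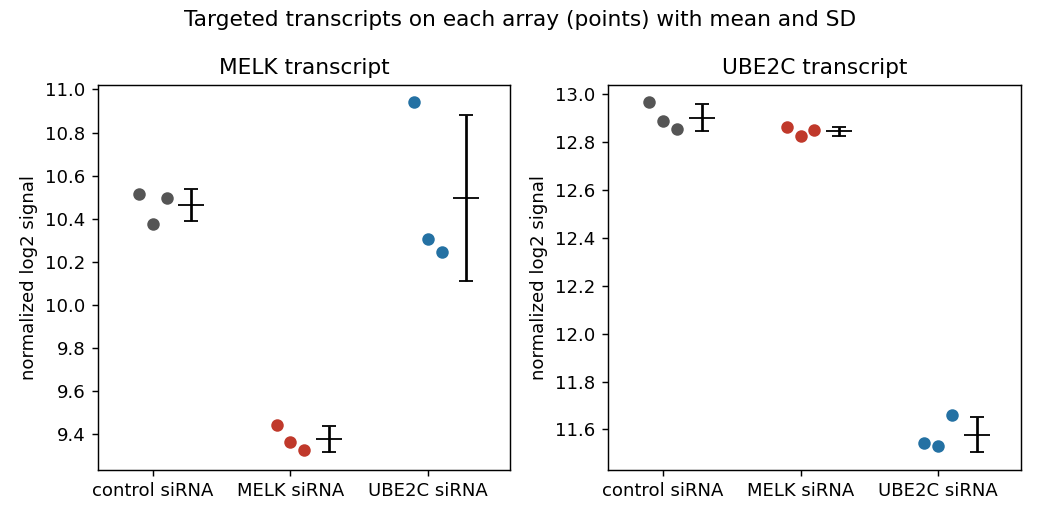
Normalized log2 signal of the MELK transcript (left) and the UBE2C transcript (right) on each array; points are arrays, and the bar beside each group is its mean with SD over 3 arrays. MELK lies at 9.38 on average with MELK siRNA against 10.46 with control siRNA, and UBE2C at 11.58 with UBE2C siRNA against 12.90.

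One array stood apart from the rest. The log2 values of UBE2C siRNA replicate 1 correlated across probes at 0.876 to 0.896 with the other arrays, which correlated with each other at 0.984 to 0.992 (probes are not independent replicates). For 641 genes with a pair of bright probes, the difference between the probes departed from its mean on other arrays with an SD of 1.96 log2 units on that array and 0.153 to 0.284 on the others. Its UBE2C transcript was nonetheless as low as in the other arrays of its group. With this array the residual SD was larger for 83.9% of genes, with a median of 0.31 log2 units against 0.17 without it. The comparisons are therefore also given in an 8-array fit, which leaves the array out and lets limma's prior spread follow signal level, with robust estimation. This combination was chosen after seeing the data, including the number of genes it called. Neither change alone gave those calls: leaving out the array called 1 gene in each comparison, and the trended, robust prior on 9 arrays called 0 genes for MELK siRNA and 1 for UBE2C siRNA. Array weights, an alternative set before the data were examined, called 126 genes for MELK siRNA and 528 for UBE2C siRNA on 9 arrays. The weight was 0.047 for UBE2C siRNA replicate 1, against 3.36 and 1.20 for replicates 2 and 3. These calls thus also come close to leaving out replicate 1.

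**Figure D2:**
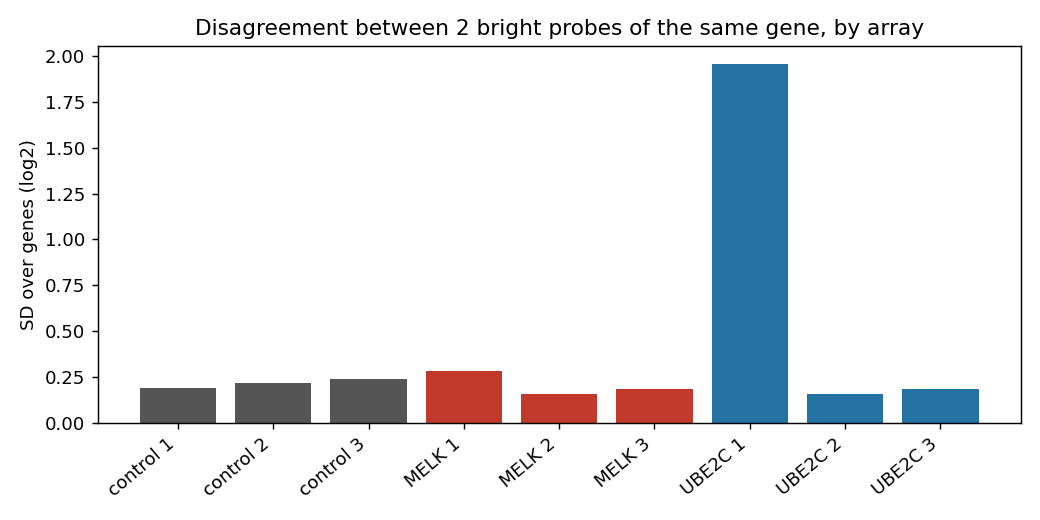
Bars show, for each array, the SD over 641 genes of the difference between 2 bright probes of the same gene, measured from the mean difference on the other arrays (log2 units, axis from 0). UBE2C siRNA replicate 1 reaches 1.96, and the other 8 arrays lie between 0.153 and 0.284.

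With MELK siRNA against control siRNA, the 8-array fit put 262 genes higher and 368 lower. The largest increases were of TRAM1L1 (log2 fold change 1.15, SE 0.30, adjusted p = 0.0359, above background on 1 of 3 controls), TSN, which encodes the nucleic acid binding protein translin (1.07, SE 0.24, adjusted p = 0.0189), RPEL1 (0.95), TMA16 (0.95, above background on 2 of 3 controls), the DNA primase subunit PRIM2 (0.90), the actin-capping subunit CAPZA1 (0.90, SE 0.15, adjusted p = 0.00402) and the pyruvate dehydrogenase phosphatase PDP1 (0.89). RANGRF was not well above background in the controls, and its fitted log2 fold change was 0.96 (1.95-fold, adjusted p = 0.044). The largest decreases were of NPIPB3 (-1.48, SE 0.18, adjusted p = 0.00126), NBPF9 (-1.21), the microtubule-associated protein gene MAP1B (-1.19), MELK itself (-1.09, SE 0.09, adjusted p = 7.82e-06), NBPF10 (-1.08), the transcription factor ZFHX3 (-1.07, SE 0.16, adjusted p = 0.00293) and the zinc finger gene ZNF526 (-1.03). SLC6A16 was not well above background with MELK siRNA and was at least 1.88-fold lower (adjusted p = 0.0398). This bound was set on each array against the lowest signal among probes above background or the probe's own signal, whichever was higher. NPIPB3, NBPF9 and NBPF10 belong to families of near-identical copies, so the copy is uncertain, and the other kept probes of NBPF10 gave -0.17 and -0.14. MAP1B was above background on 1 of 3 MELK siRNA arrays, and was at -0.77 without control replicate 3.

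In the fit of all 9 arrays, limma called 0 genes for MELK siRNA against control, and 616 genes had an unadjusted p under 0.05, where 571.4 are expected by chance. The arrays of the groups did not overlap for 25.7% of genes, where chance gives 10% for 3 against 3. The 8-array count fell to 41 higher and 12 lower with median scaling, which turned the majority from lower to higher, to 175 genes with the detection filter read literally, to 282 without a filter, to 356 with only 2 groups in the fit and to 1 gene without the trended prior. It was 977 with array weights and 1313 with a covariate for the direction in which UBE2C siRNA replicate 1 departed. It was 78 without MELK siRNA replicate 2, 185 without replicate 3, 418 without control replicate 1, 364 without control replicate 2, and 356 without either remaining UBE2C siRNA array.

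Mitochondrial respiratory chain genes were higher as a group with MELK siRNA in camera at the preset correlation. Of 46 measured members 39 had a positive log2 fold change, with a median of 0.09, and 5 rose in the 8-array fit (6 adjusted over the list alone) while 0 fell. The complex I subunits NDUFA9 (0.49, SE 0.08) and NDUFB9 (0.41, SE 0.06), the complex III subunit UQCRC2 (0.46, SE 0.09) and the complex II subunit SDHD (0.45, SE 0.12, and 0.30 without control replicate 2) rose most. The list was called by camera with 9 arrays (adjusted p = 0.0253) and with 8 (adjusted p = 0.000975). With an estimated correlation the adjusted p was 0.50 and 0.305. With 9 arrays the adjusted p was 0.107 without control replicate 2 and 0.120 without control replicate 3. It was 0.0765 without MELK siRNA replicate 2 and 0.109 after cyclic loess. Of the 10 splits of these 6 arrays, the labelled one included, 2 called at least 1 list with 9 arrays. In the 8-array fit 4 of 10 did, and another split called 3. A call of 1 list is therefore not more than other splits gave.

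The other 21 of the 22 lists were not called by camera for MELK siRNA, and the changed members went both ways in several. The fry test, which does not compare a list with other genes, called respiratory chain and cholesterol genes higher on balance (adjusted p = 0.0272 for each) in the 8-array fit. It called hypoxia and glycolysis genes and androgen-responsive genes (adjusted p = 0.0272 for each) and immediate-early genes (adjusted p = 0.029) lower. Of 80 mitosis genes 3 rose and 1 fell in the 8-array fit (3 and 2 adjusted over the list alone), with a median of 0.02 and a mean of -0.02: the kinetochore motor CENPE was lower (-0.97, SE 0.22) and the mitotic kinase PBK higher (0.47, SE 0.10). Of 64 DNA replication genes 6 rose and 3 fell (7 and 6 adjusted over the list alone), among them PRIM2 (0.90) and UHRF1, which recruits maintenance methylation to replicated DNA (-0.46). The repair scaffold SLX4 fell (-0.74) and RMI1 of the BLM helicase complex rose (0.48), the only calls but 1 among 31 recombination and Fanconi genes. Of 31 substrates of the anaphase-promoting complex, the replication licensing inhibitor GMNN (0.43) and the centrosomal kinase NEK2 (0.33, and 0.10 on a second probe) rose. The p53 targets RRM2B (0.68) and TIGAR (0.45) rose with 1 other of 33, although a second RRM2B probe gave -0.07. IFIT5 rose (0.56) and IFIT1 fell (-0.50) among 44 interferon-stimulated genes. TNIP1 (-0.46) and NFKB1 (-0.32) fell among 30 inflammatory genes.

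Of 26 cholesterol synthesis and uptake genes 3 rose and 1 fell with MELK siRNA in the 8-array fit (7 and 2 adjusted over the list alone), led by the sterol demethylase CYP51A1 (0.66, SE 0.12) and the isomerase IDI1 (0.48, SE 0.12). NDRG1 (-0.53) and the carbonic anhydrase CA12 (-0.53) fell among 32 hypoxia and glycolysis genes, although a second CA12 probe gave -0.01, and NDRG1 was also the 1 call among 16 androgen-responsive and luminal markers. Of 38 autophagy and lysosome genes 4 fell, including the lysosomal protease CTSB (-0.83, SE 0.12, and -0.54 on a second probe) and ATG2A (-0.43). CLDN3 (-0.45) and SDC1 (-0.29) fell among 23 epithelial markers, COL5A1 (-0.59) among 32 mesenchymal and matrix genes, and ZFP36 (-0.68) and PHLDA1 (-0.33, and -0.16 on a second probe) among 27 immediate-early genes. UBE2Q2 rose (0.38) among 25 ubiquitin-conjugating enzymes. Adjusted over the list alone, 5 inflammatory genes, 3 epithelial markers and 2 mesenchymal and matrix genes fell, 1 immediate-early gene rose and 4 fell, 1 autophagy and lysosome gene rose and 5 fell, 2 ubiquitin-conjugating enzymes rose and 1 fell, 1 androgen-responsive gene rose and 1 fell, and 1 fibroblast, endothelial or blood cell marker fell; the other lists gave the same counts. Over all genes, no call was made among regulators and subunits of the anaphase-promoting complex, AMPK-related kinases, apoptosis regulators, unfolded protein response genes, ribosomal protein genes, or markers of fibroblasts, endothelium and blood cells.

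With UBE2C siRNA against control siRNA, the 8-array fit put 192 genes higher and 318 lower. Small nucleolar RNAs led the increases: SNORD46 (1.34, SE 0.23, adjusted p = 0.0119), SNORA23 (1.14, above background on 1 of 3 controls, and 0.68 without UBE2C siRNA replicate 2), SNORA80E (1.13), SNORD13 (1.13, SE 0.12, adjusted p = 0.000176) and SNORD3C (1.11), the last with near-identical copies. GCH1, the first enzyme of tetrahydrobiopterin synthesis, rose by 1.02 (SE 0.20, adjusted p = 0.0143) and the Golgi transport gene GOLT1B by 1.01, and ETV3, not well above background in the controls, was at least 2.02-fold higher. The largest decreases were of UBE2C (-1.31, SE 0.08, adjusted p = 4.15e-08), NPIPB3 (-1.28), the giant Golgi protein gene GOLGB1 (-1.14, SE 0.22, adjusted p = 0.0143), CENPE (-1.04, SE 0.24, adjusted p = 0.028), NBPF9 (-0.97) and TENM3 (-0.96). COL20A1 was at least 2.11-fold lower, and the centrosomal gene CNTROB had a fitted log2 fold change of -1.05 (2.08-fold lower). Neither was well above background on the remaining UBE2C siRNA arrays. Several values were smaller with all 9 arrays, where the log2 fold change was 0.20 for GCH1, 0.56 for GOLT1B, 0.65 for ETV3 and -0.75 for COL20A1. All the small nucleolar RNAs named above were instead larger with UBE2C siRNA replicate 1 added. The log2 fold change was then 1.86 for SNORD46, 1.54 for SNORA80E, 1.28 for SNORD13 and 1.19 for SNORD3C, and SNORA23 was larger too. None of these RNAs was called with all 9 arrays.

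In the fit of all 9 arrays, limma called 1 gene for UBE2C siRNA against control, UBE2C itself, and 1274 genes had an unadjusted p under 0.05. The 8-array calls rest on both remaining UBE2C siRNA arrays: 2 genes were called without replicate 2 and 5 without replicate 3. The count was 148 without control replicate 2 and 255 without MELK siRNA replicate 2. It was 8 higher and 2 lower with median scaling, again turning the majority, 4 genes with the detection filter read literally, 211 without a filter, 219 with the covariate for the departing array and 1 without the trended prior. It rose to 768 with detection on all arrays and to 1022 with array weights.

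With UBE2C siRNA, camera called 4 lists in the 8-array fit, each close to the threshold. Of 46 respiratory chain genes 33 were positive and 4 rose (4 adjusted over the list alone): SDHD (0.55), NDUFB9 (0.43), the ATP synthase subunit ATP5F1C (0.41) and NDUFA9 (0.36); the list's adjusted p was 0.0468, and 0.450 with an estimated correlation. Of 65 ribosomal protein genes 48 were positive and 0 passed the test singly (adjusted p = 0.0488 for the list, and an adjusted p of 0.440 with an estimated correlation). Of 32 mesenchymal and matrix genes 3 fell (9 fell and 2 rose adjusted over the list alone): the collagen VI chains COL6A3 (-0.44) and COL6A1 (-0.42) and the protease inhibitor TIMP1 (-0.36); the list's adjusted p was 0.0488, and 0.450 with an estimated correlation. Of 27 immediate-early genes, FOSL1 (-0.40) and IER3 (-0.31) fell and the phosphatase DUSP6 rose (0.42), with a list adjusted p of 0.0488, and an adjusted p of 0.440 with an estimated correlation (1 rose and 5 fell adjusted over the list alone). The fry test called the immediate-early list lower (adjusted p = 0.0281) and none of the others. With all 9 arrays the log2 fold change was 0.09 for ATP5F1C, 0.84 for SDHD, -0.14 for TIMP1 and -0.53 for IER3. The ribosomal protein genes then had a median of 0.02 and a mean of -0.11, with the list lower in camera and not called (adjusted p = 0.747), and the respiratory chain (adjusted p = 0.123) and immediate-early (adjusted p = 0.0874) lists were not called either. The number of lists called was 0 after cyclic loess, with array weights, with detection on all arrays, with only 2 groups in the fit and without the trended prior. It was also 0 without control replicate 3, MELK siRNA replicate 1, MELK siRNA replicate 3 or UBE2C siRNA replicate 2, 2 without control replicate 2, and 1 without UBE2C siRNA replicate 3, without background correction, with normexp or with the authors' values.

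With all 9 arrays, epithelial markers (adjusted p = 0.00768) and mesenchymal and matrix genes (adjusted p = 0.0125) were lower as groups with UBE2C siRNA, and the adjusted p was 0.557 and 0.432 with an estimated correlation. UBE2C siRNA replicate 1 decided the call of epithelial markers: their median on that array was -1.08 relative to the rest of its group, where all genes had a median of 0.33, and without it the adjusted p was 0.292 (0.426 with array weights). The median of the mesenchymal and matrix genes was 0.02 there; their adjusted p was 0.0666 without that array, 0.0776 without control replicate 3, 0.0894 with median scaling, 0.0703 with array weights and 0.0488 in the 8-array fit. In the 8-array fit 2 of 23 epithelial markers fell, ITGB4 (-0.72, and -0.30 on a second probe) and SDC1 (-0.37).

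Among the lists not called by camera with UBE2C siRNA, 3 of 80 mitosis genes rose and 3 fell (4 and 6 adjusted over the list alone), with a median of -0.03; CENPE (-1.04) and the spindle pole gene ASPM (-0.79, SE 0.15) fell most. Of 64 DNA replication genes 1 rose, the clamp loader subunit RFC3 (0.55, and 0.51 and 0.27 on other probes), and 5 fell, including MCM8 (-0.52, and -0.29 without UBE2C siRNA replicate 2). Of 20 regulators and subunits of the anaphase-promoting complex, the checkpoint protein gene MAD2L1 (0.48, SE 0.11) and the subunit ANAPC13 (0.36, SE 0.10) rose, while 0 of its 31 substrates were called. With all 9 arrays MAD2L1 was at -0.25 (SE 0.53, adjusted p = 0.837), so its direction rests on leaving out UBE2C siRNA replicate 1. Among ubiquitin-conjugating enzymes UBE2Q2 rose (0.45) and UBE2O fell (-0.57). TNIP1 (-0.55) and IER3 (-0.31) fell among inflammatory genes, CTSB (-0.66), ATG2A (-0.53) and another 2 fell among autophagy and lysosome genes, and the p53 target RPS27L rose (0.31). IDI1 rose (0.61) and the fatty acid synthase FASN fell (-0.49) among cholesterol and lipid synthesis genes, and MTHFD2 rose (0.49) and STC2 fell (-0.45) with another 2 among 45 stress response genes. With all 9 arrays the log2 fold change was 0.35 for RFC3, -0.30 for MCM8, 0.73 for UBE2Q2, -0.26 for UBE2O, -0.25 for TNIP1, -0.53 for IER3, -0.40 for CTSB, -0.29 for ATG2A, 0.46 for RPS27L and -0.25 for STC2, none of them called. Adjusted over the list alone, 4 DNA replication genes rose and 8 fell, 1 substrate of the anaphase-promoting complex rose and 3 fell, 6 cholesterol genes rose and 1 fell, 2 stress response genes rose and 6 fell, 1 androgen-responsive gene rose and 5 fell, 1 ubiquitin-conjugating enzyme rose and 2 fell, 3 inflammatory genes, 5 autophagy and lysosome genes and 5 epithelial markers fell, and 0 p53 targets were called; the other lists gave the same counts. Over all genes, no call was made among recombination and Fanconi, AMPK-related kinase, apoptosis, interferon-stimulated, hypoxia, androgen-responsive, or fibroblast, endothelial and blood cell genes.

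Compared directly, the knockdowns differed in their own targets, the 2 single genes that passed the test. In the 8-array fit limma called these 2 genes between MELK siRNA and UBE2C siRNA: UBE2C (1.25, SE 0.08, adjusted p = 8.46e-08) and MELK (-0.90, SE 0.10, adjusted p = 0.00036). An unadjusted p under 0.05 was found for 581 genes, where 571.4 are expected by chance, and the median half-width of a gene's unadjusted 95% interval was 0.33 log2 units. The call of UBE2C was lost with the mean of probes (adjusted p = 0.913), and that of MELK with median scaling (adjusted p = 0.0683), without the trended prior (adjusted p = 0.0976) and without UBE2C siRNA replicate 2 (adjusted p = 0.0528). In the fit of all 9 arrays, 1 gene was called, UBE2C (1.27, SE 0.12, adjusted p = 0.0401), and 336 had an unadjusted p under 0.05. No gene was called with 9 arrays after median scaling, with the mean of probes, every probe or only 2 groups in the fit, or when any array other than UBE2C siRNA replicate 1 was left out. None of the 22 lists was called with 8 arrays. With 9 arrays epithelial markers were higher with MELK siRNA (adjusted p = 0.00273, and an adjusted p of 0.666 with an estimated correlation), and UBE2C siRNA replicate 1 decided that call too: without it the adjusted p was 0.870 (0.859 with array weights).

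Both knockdowns moved genes in the same direction away from the control siRNA, which came from another supplier than both pools. In the 8-array fit 107 genes were higher and 193 lower in both, against 4.4 and 10.2 for independent lists, and 0 were called in opposite directions. NPIPB3 (-1.48 with MELK siRNA and -1.28 with UBE2C siRNA), NBPF9 (-1.21 and -0.97), CENPE (-0.97 and -1.04), NPIPB5 (-0.85 and -0.91), GOLGB1 (-0.83 and -1.14) and the myosin gene MYO9B (-0.82 and -0.85) fell most in both; NPIPB5 too has near-identical copies, and was at -1.56 with UBE2C siRNA when all 9 arrays were used. Across genes, which are not independent replicates, the fold changes correlated at 0.694. Unchanged groups simulated against the same controls gave a mean of 0.448 and a largest value of 0.477 in 100 draws, and 0 genes called in both. The covariance was 0.0529 against 0.0162 simulated, a difference of 0.0366. With 9 arrays 0 genes were called in both (0.06 on average when simulated), the correlation was 0.508 against 0.503 simulated, and the covariance was 0.0587 against 0.0515. That simulation took its spreads from the fit with UBE2C siRNA replicate 1, which is not a control. Its covariance was therefore larger than the 0.0162 simulated with 8 arrays, and the near match cannot show that the resemblance is absent. In both simulations the genes varied independently, so a deviation of the controls shared by many genes could not arise. The 3 controls cannot be split into parts of 2 arrays, so part or all of the excess may come from the shared controls. The overlap of 300 genes in the 8-array fit was 1 without UBE2C siRNA replicate 2, 4 without replicate 3, 51 without MELK siRNA replicate 2, 128 without MELK siRNA replicate 3, and 32 higher and 72 lower without control replicate 2. It was 6 with median scaling, 3 with the detection filter read literally, 123 without a filter, 191 with only 2 groups in the fit, 163 with the covariate for the departing array, 0 without the trended prior and 567 with array weights.

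**Figure D3:**
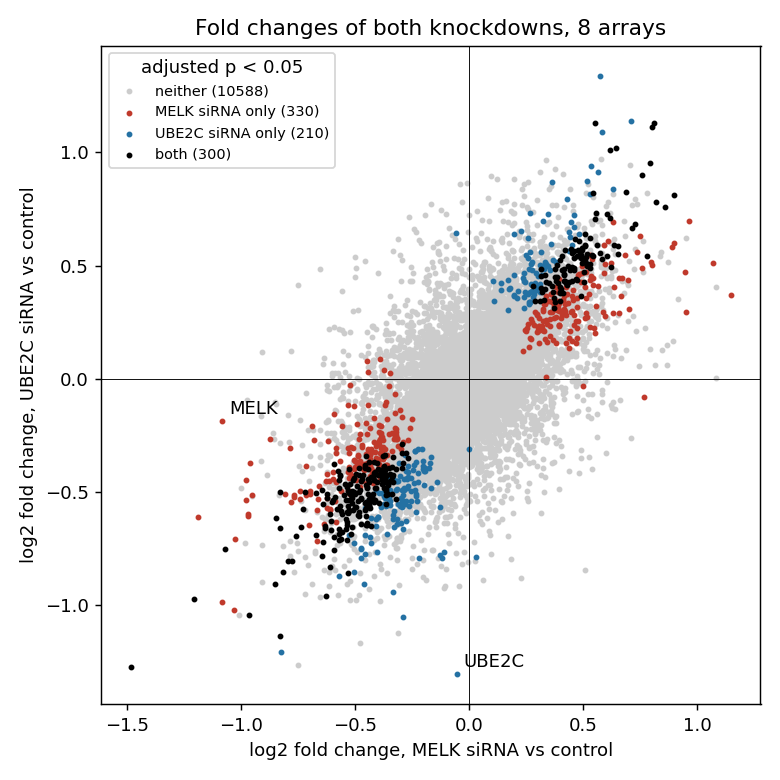
Each point is 1 of 11428 genes in the 8-array fit, with its log2 fold change for MELK siRNA against control on the x axis and for UBE2C siRNA against control on the y axis; colours mark genes called in neither, one or both. The 300 genes called in both lie in the quadrants of equal sign, and MELK and UBE2C lie apart on their own axes.

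**Figure D4:**
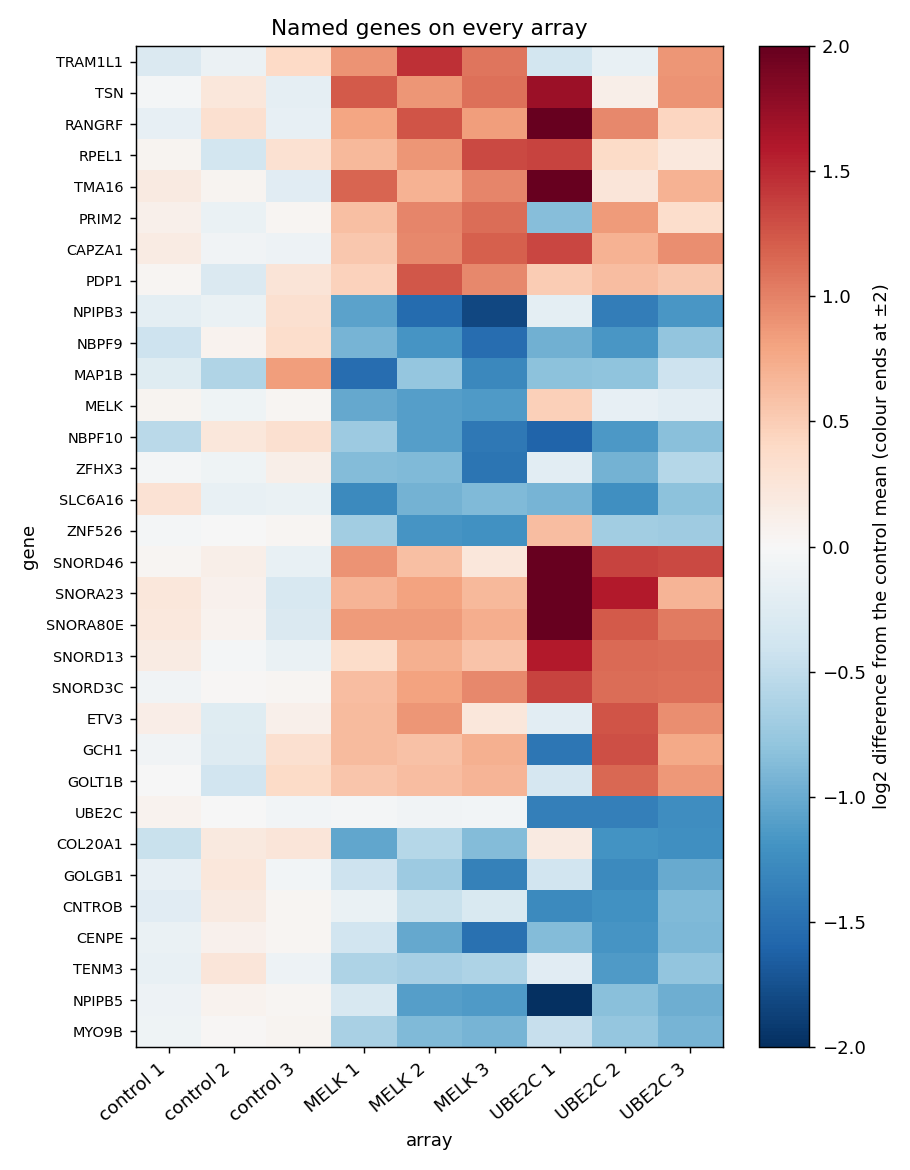
Log2 difference of each named gene (rows) from the mean of the 3 controls on each of the 9 arrays (columns), red higher and blue lower, with the colour ending at 2 log2 units. NPIPB3, CENPE and GOLGB1 are blue on the MELK siRNA arrays and on UBE2C siRNA replicates 2 and 3, while UBE2C siRNA replicate 1 departs from its group for many genes.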

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

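Probes without a listed gene, which the comparisons do not use, were tested among all 19511 kept probes in the 8-array fit, a test chosen after seeing the data. Of 4445 such probes, 133 passed the threshold for MELK siRNA against control (81 higher and 52 lower), 72 for UBE2C siRNA against control (34 higher and 38 lower) and 1 between the knockdowns. In the fit of all 9 arrays 0 of them passed in any comparison. The genes these probes measure were not identified here.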

How the results depend on the processing

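Values are given in the order MELK siRNA against control, UBE2C siRNA against control, and MELK siRNA against UBE2C siRNA, and the cause of a change was not tested unless stated. The 8-array fit and its alternatives, the background taken from near-background signals and the signal-loss covariate were chosen after seeing the data. So were the detection filter of the main results and setting the named genes of the 8-array fit against all 9 arrays. The literal detection filter was the one fixed beforehand.

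With 9 arrays the counts were 0, 1 and 1. Array weights gave 126, 528 and 6, an overlap of 87, a called MELK (-1.09) and 0 lists for the last 2 comparisons. The 8-array fit gave 630, 510 and 2, an overlap of 300, a called MELK (-1.09), and 4 and 0 lists in the last 2 comparisons. The call of UBE2C was lost, leaving 0 and 0 in the last 2 comparisons, with median scaling (-1.03), the mean of probes (-0.77), only 2 groups in the fit (-1.32) and a threshold of 0.01 (-1.32); testing every probe, which defines no lists or targets, also left 0 and 0. Lists called against 1, 2 and 1 were 0 in the first comparison after cyclic loess, 0 and 1 in the first 2 at a threshold of 0.01, and 0 throughout with an estimated correlation or fry. The second was 4 without a detection filter, with the literal filter and with the trended prior, and the third was 2 without a filter and with detection on all 9 arrays. Leaving out 1 array gave 0 to 1, 0 to 1 and 0 to 1 genes, MELK from -1.13 to -1.06, UBE2C from -1.37 to -1.29, and 0 to 1, 0 to 2 and 0 to 2 lists.

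In the 8-array fit, the counts and the overlap changed from 630, 510, 2 and 300. Array weights gave 977, 1022, 4 and 567, and 0 lists for UBE2C siRNA. Median scaling gave 53, 10, 1 and 6, with 3 lists for MELK siRNA and 1 in the direct comparison; it moved the median of all genes to 0.09 and 0.04, and to 0.11 for UBE2C siRNA with 9 arrays. No filter gave 282, 211 and an overlap of 123. The literal filter gave 175, 4 and an overlap of 3, with 2 lists for MELK siRNA. Detection on all arrays gave 768 for UBE2C siRNA, with 0 lists. Only 2 groups in the fit gave 356 and an overlap of 191, with 0 lists for UBE2C siRNA. A threshold of 0.01 gave 105, 9 and an overlap of 7, with 0 lists for UBE2C siRNA, and a log2 fold change of at least 1 gave 10, 14, 1 and 1. No trend gave 1, 1, 1 and 0, with 0 lists for UBE2C siRNA. The signal-loss covariate gave 1313, 219 and an overlap of 163, with 1 list in the direct comparison. The mean of probes gave 1 in the direct comparison and 3 lists for MELK siRNA, and every probe gave 4 in the direct comparison. Lists for UBE2C siRNA, 4 here, were 1 without background correction, with normexp, with the authors' values and with fry, and 0 with cyclic loess, which gave 1 in the direct comparison, or an estimated correlation, which gave 0 for MELK siRNA where fry gave 5. Leaving out 1 array gave 78 to 692, 2 to 755 and 1 to 2 genes, 1 to 404 in the overlap, and 1 to 2, 0 to 4 and 0 to 1 lists. Where 1 UBE2C siRNA array is left, it is assumed to vary like the other groups.

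Of the 93 values of named genes in the 8-array fit, 1 changed sign in a setting run here: MAD2L1 with UBE2C siRNA was -0.25 with all 9 arrays, through the added UBE2C siRNA replicate 1. With all 9 arrays another 91 lost their call, and 0 of 47 values for MELK siRNA, 19 of 44 for UBE2C siRNA and 0 of 2 in the direct comparison moved by over 1.5 times. Calls were lost by 92 without the trend, 76 with the literal filter, 71 with median scaling, 63 without UBE2C siRNA replicate 2, 62 without replicate 3 and 59 without MELK siRNA replicate 2.

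The replicate block left 0 genes in place of 1 for UBE2C siRNA and in the direct comparison with 9 arrays (UBE2C -1.32), and gave 337 for UBE2C siRNA and 1 list in the direct comparison with 8. Of 9 same-numbered pairs 4 correlated over 0.1 (-0.13 to 0.25), so the numbers were not taken to pair the samples. The slide as a block was not run, since no slides were known here. Signal over background limits dim genes. Those above background on no array of a group are given as bounds, except RANGRF and CNTROB, whose fitted changes are given. TRAM1L1, TMA16, MAP1B and SNORA23, above background on only 1 or 2 arrays of a group, are also fitted values.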

Other observations

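Short noncoding RNAs were higher in both knockdowns in the 8-array fit. Of 121 small nucleolar, small nuclear, Y and vault RNAs grouped by annotated class, a list made after seeing the data, 88 were positive with MELK siRNA (median 0.23, 8 called higher and 0 lower) and 94 with UBE2C siRNA (median 0.29, 15 called higher and 0 lower). Camera gave p = 1.15e-05 and p = 2.29e-11, and p = 0.0155 and p = 0.00273 with an estimated correlation, unadjusted for the choice of list. Among the largest were SNORD3D (0.79 with MELK siRNA and 0.96 with UBE2C siRNA), SNORD13 (0.55 and 1.13), RNY4 (0.69 and 0.82) and RNY1 (0.60 and 0.73), the Y RNAs being parts of Ro ribonucleoproteins; RNY3 (-0.16 and 0.22) and RNY5 (0.42 and 0.53) were not called. For the 13 small nuclear RNAs alone, camera with an estimated correlation gave p = 0.106 and p = 0.0612. SNORD3C and SNORD3D are near-copies that probes may not tell apart, and the medians were lower without background subtraction, at 0.0788 with MELK siRNA and 0.12 with UBE2C siRNA in the authors' values. Compared directly, the list was lower with MELK siRNA than with UBE2C siRNA: 33 of 121 were positive (median -0.13, and -0.07 in the authors' values), 0 were called singly, and camera gave p = 1.5e-06, and p = 0.0108 with an estimated correlation. The list's median deviation from the mean of all arrays was -0.28 to -0.18 on the controls, -0.05 to 0.12 on the other arrays of the fit and 0.68 on UBE2C siRNA replicate 1, which the fit leaves out. MicroRNA precursors and hosts (36 genes) had medians of 0.04 and 0.17 with 0 called.

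Of the tests that follow, those of the shared controls, of the normalization, of the signal-loss axis over short RNAs and of other splits were written before their results were seen; the rest were chosen after.

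UBE2C siRNA replicate 1 departed from all other arrays. RNA of another cell type or line and a response to UBE2C siRNA, each as the main cause, are argued against by pairs of bright probes of one gene, whose deviations on that array correlated at 0.23 across 641 genes, against 0.667 and 0.714 for the knockdown differences on other arrays. The SD of probe pair differences was 6.91 times the highest of the other arrays, with 162 genes off by over 2 log2 units, which is consistent with signal lost unevenly between probes. What would cause such a loss stays open.

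Both knockdowns departed from the control alike. Of 100 simulated draws of unchanged groups against the shared controls, 0 had a covariance as large as 0.0529 (highest 0.0178). The draws varied each gene independently, so they argue only against spread of that kind as the whole cause. A deviation of the controls shared by many genes could not arise in them, and the shared controls stay open. The signal-loss axis of UBE2C siRNA replicate 1 as the main cause is argued against by its correlation of 0.0587 across genes with the difference of MELK siRNA from control. A covariate for that axis lowered the overlap but left genes called in both. The axis is the difference of that array from the rest of its group, which itself lowers the scores of those arrays (-0.029 and -0.038). The covariate is thus tied to the UBE2C siRNA group, and the lower overlap cannot show that signal loss had a part. Such a part is not excluded either. A difference in handling or siRNA type cannot be told apart from a shared response to the knockdowns, because the series has 1 negative control siRNA, from another supplier than both pools per the labels. A shared biological response stays open as a hypothesis.

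The rise of short noncoding RNAs may come in part from the normalization. Its lowest median with MELK siRNA was 0.0788, in the authors' values, which are not background-subtracted. This lay below the bound of 0.1 set beforehand, although the median was positive in all 8 normalizations. The list is dim (median log2 signal 5.64 to 5.99 on the 8 arrays), and background left in shrinks changes of dim probes whatever their cause. The test therefore cannot show that the normalization made the rise. The signal-loss axis correlated at 0.102 with the difference of MELK siRNA from control over the 121 members. A rise common to all members does not enter that correlation, so the test cannot decide. The list's median deviation was highest on UBE2C siRNA replicate 1 itself (0.68). Recovery of short RNA that differed between extracts cannot be told apart from a response, because the lowest knockdown array lay 0.133 above the highest control array and no measure of recovery was analysed here. A biological rise remains an untested hypothesis.

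The 6 arrays of a pair of groups make 10 splits, too few for a share under 0.05. For MELK siRNA against control with 9 arrays, the labelled split called 0 genes and the highest other 0 (10 of 10 splits gave as many), and 1 list against 1 (2 of 10). For UBE2C siRNA it called 1 gene against 0 (1 of 10) and 2 lists against 2 (3 of 10), and between the knockdowns 1 gene against 0 (1 of 10) and 1 list against 2 (7 of 10). In the 8-array fit of MELK siRNA against control it called 630 genes against 29 (1 of 10) and 1 list against 3 (4 of 10).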
